A study of Rattus norvegicus with 12 samples.

How the data were processed

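RNA from rat proximal aorta and semilunar valves, neonatal and adult, was measured on 12 Affymetrix arrays, 3 in each of 4 groups, per the labels. RNA was extracted with Trizol and RNeasy columns, and poly-A RNA was labelled in a T7 in vitro transcription reaction with the Affymetrix IVT Labeling Kit, per the labels' protocols. The deposited values are intensity values, the signal per probe set on a linear scale, made by the authors with Affymetrix Expression Console and the MAS5 algorithm, per the submitters' processing notes. Versions of these programs and the scaling target are not given in the sources used here. The values show 1 scale factor per array: the mean after trimming 2% at each end was 500.1 to 500.2 on every array. Raw image files and detection calls were not used here.

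The table held 31099 probe sets. The 57 control probe sets were left out of the tests, which left 31042. Gene names came from the probe set table of the array, with 20826 probe sets given 1 symbol (20758 of them matched by gene ID to the reference), 436 several and 9780 none. Signals below 1 were set at 1 (12 to 185 probe sets per array), and log2 was taken, with no further normalization. Probe sets were kept where the signal was above 171.944, the median of all values (7.43 in log2), on at least 3 of the 12 arrays. This kept 18552 probe sets (59.8%), of which 14065 had 1 symbol, for 10411 genes. Precision is limited by 3 arrays per group. Spearman correlations between arrays of a group were 0.948 to 0.960 for neonatal aorta, 0.812 to 0.925 for adult aorta, 0.926 to 0.953 for neonatal valve and 0.916 to 0.953 for adult valve.

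Groups followed the sample titles, which the source names match. In 6 samples the description and tissue entries name another group, and the alternative grouping is given in the closing section. A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, 8 residual degrees of freedom). The contrasts were adult against neonatal aorta, adult against neonatal valve, neonatal valve against neonatal aorta, adult valve against adult aorta, and the age difference in valve minus that in aorta. A probe set passed at an adjusted p under 0.05 (Benjamini and Hochberg over the probe sets tested, two-sided). The count with a change of at least 2-fold as well is given beside it. Errors are standard errors of the fit.

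The 27 gene lists were fixed before the values were seen and were tested with camera of limma at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Of 670 listed genes, 500 were tested. Each gene was represented by its probe set with the highest mean. The lists covered cell cycle, imprinted and fetal growth genes, collagens, elastic fibre, basement membrane, proteoglycans, cartilage, bone, smooth muscle, cardiac muscle, endothelium, adipocytes, red blood cells, macrophages, lymphocytes, antigen presentation, and melanocytes and Schwann cells. They also covered Wnt, BMP and TGF-beta, Notch, valve and outflow transcription factors, clock, immediate early genes, fatty acid oxidation, proteases and inhibitors, vasoactive genes and Hox genes. Another 3 lists (skeletal muscle, squamous epithelium, thymocytes) were added after the data were seen and serve only to describe single arrays.

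Genes were named by a rule fixed beforehand. In each comparison of 2 groups these were the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol, with 1 probe set per gene. The arrays of the groups did not overlap, and the higher group's mean was at least 1 in log2 above the median of all values. For the difference between age differences they were up to 6 each way. Up to 4 list members by smallest adjusted p were eligible from each list. Of these members, the ones printed were selected after their values were seen. Sex chromosome genes served to check the labels.

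The fit was tested on simulated arrays with the real means and spreads, 200 of 18552 probe sets changed in each of 10 draws. A first test with 1 draw per comparison gave shares of false calls that were too imprecise, and the number of draws was then raised. For changes of 1, 2 and 4 in log2, the shares recovered were 19.3%, 64.5% and 89.8% for the aorta by age, and 18.7%, 64.2% and 91.5% for the valve by age. They were 17.8%, 64.0% and 90.2% between neonatal tissues and 14.3%, 63.4% and 90.9% between adult tissues. For the difference of age differences they were 2.39%, 35.5% and 76.7%. False calls were 4.63%, 5.77%, 4.59%, 4.76% and 5.71% of calls, in the order of the contrasts above. With the elastic fibre list shifted by 1 in the comparison of aorta by age (10411 genes), that list was found and 0 of 26 others were called. Simulated genes were drawn independently, with 1 spread per probe set for all groups. The simulation therefore does not show how the tests behave with correlated genes or with groups of unequal spread. In the data the elastic fibre list had an estimated correlation of 0.35 in that comparison.

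Alternatives planned beforehand were quantile normalization, centring each array on its median, no filter, a filter at the 75th percentile, log2 of the signal plus 32, no intensity trend, the replicate number as a block, only the groups compared, 1 probe set per gene, each array left out in turn, and groups by description and tissue. Alternatives added after seeing the data left out adult aorta 1 and neonatal valve 3 together, or left out neonatal aorta 2 and 3, which lack the added poly-A control RNAs, or took the presence of those controls as a block. Ratios of 3' to 5' control probe sets were compared by exact permutation of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were summarized with pandas 2.3.3.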

Results

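Gene expression was measured on 12 oligonucleotide arrays with RNA from Wistar rats. By their titles the arrays formed 4 groups of 3: neonatal aorta, adult aorta, neonatal valve and adult valve. The aorta samples were the proximal part of the vessel, the valve samples were the aortic and pulmonary semilunar valves, and the neonatal tissue was collected within 24 h of birth. The median signal per array ran from 182 to 202 on aorta arrays and from 133 to 169 on valve arrays, at a trimmed mean of 500.1 to 500.2 on every array. The number of arrays limits the precision of each value. Nothing in the labels says that the replicates of a group came from separate animals, so every p-value measures only the spread between these samples. The comparisons ask how expression differs between newborn and adult life in each tissue, whether that difference is itself different in valve and aorta, and how valve and aorta differ at each age.

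The labels of 6 samples conflicted. The 3 arrays titled adult aorta carried a description and a tissue entry of neonatal valve, and the 3 titled neonatal valve carried those of adult aorta, while title and source name matched in all of them. Groups follow the title. Igf2, which encodes a growth factor of fetal life, had signals of 17222 to 20768 on neonatal aorta arrays and 184 to 376 on adult valve arrays. On the arrays with conflicting labels they were 339 to 879 where the title was adult aorta and 6189 to 8898 where it was neonatal valve. Xist, the RNA that coats the inactive X chromosome of female cells, had signals of 5.08 to 297 on neonatal aorta arrays and 15.9 to 25.2 on adult aorta arrays. The valve arrays had 10998 to 15809 at the neonatal and 12355 to 18362 at the adult age. Eif2s3y, a Y-linked translation factor gene, had signals of 1379 to 2557 on the aorta arrays, 3.32 to 134 on neonatal valve arrays and 1.39 to 8.91 on adult valve arrays. Of the probe sets of Uty, another Y-linked gene, one went the other way, with 580 to 764 on aorta arrays and 1275 to 2695 on valve arrays. The dimmer one had 34.5 to 113 on aorta arrays and 15.7 to 38.9 on valve arrays. The adult samples are labelled male.

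**Figure D1:**
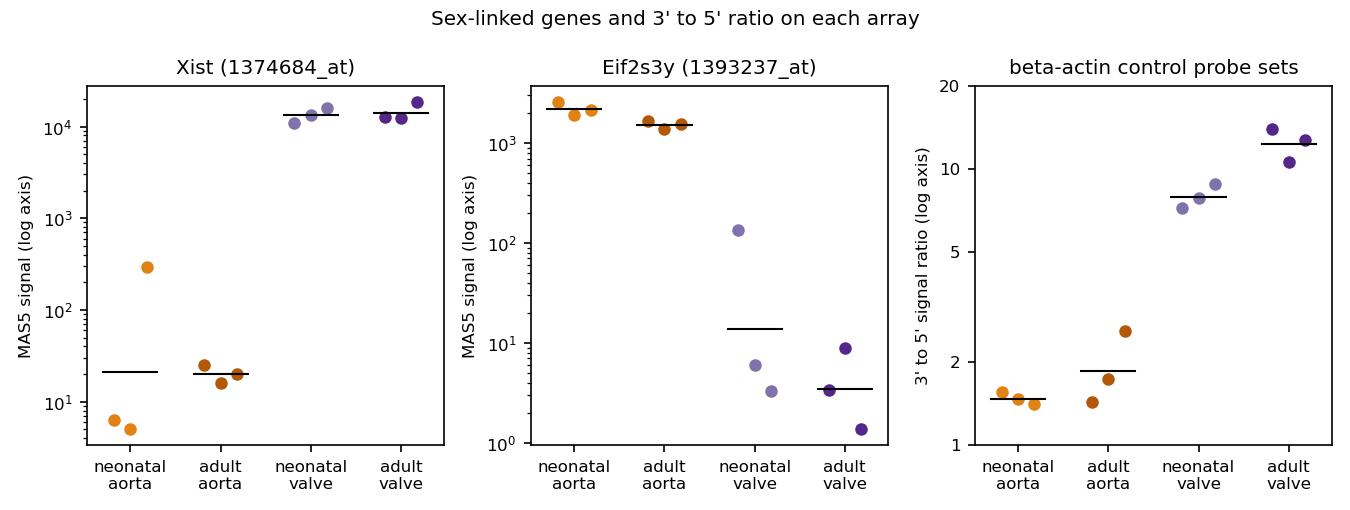
MAS5 signal of Xist and Eif2s3y and the 3' to 5' signal ratio of the beta-actin control probe sets, each on a log axis, for the 12 arrays in 4 groups (points are arrays, lines are geometric means). Xist was at least 10998 on every valve array and at most 297 on every aorta array, and the ratio was 7.24 to 13.99 on valve arrays and 1.40 to 2.59 on aorta arrays.

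Valve and aorta arrays also differed in how evenly transcripts were covered. The ratio of the 3' to the 5' probe set of beta-actin, a housekeeping gene used to judge RNA and labelling, had a geometric mean of 1.66 on the 6 aorta arrays and 9.92 on the 6 valve arrays (log2 difference 2.58, exact two-sided permutation p = 0.0022, the smallest possible). The same ratio for GAPDH, a glycolytic housekeeping gene, was 1.00 and 2.90. For dap, a bacterial control RNA added before labelling, it was 1.98 on the 4 aorta arrays that held the control and 19.3 on the 6 valve arrays. By age, the beta-actin ratio differed by 0.34 in log2 in the aorta and by 0.64 in the valve (exact permutation p = 0.3 and p = 0.1, smallest possible 0.1). Neonatal aorta 2 and 3 carried almost no signal of the added control RNAs (dap 5.82 to 13.4, against 1799 to 13879 on the other 10 arrays), and these arrays stood apart as a batch in this respect. The 3' probe sets of the 4 control RNAs read 5.82 to 54.6 there, so a signal at this level cannot be told from an absent RNA. A log2 difference from a group mean at that level is not an exact fold, and none is given for it. The main values take no account of it, and values with it as a block were computed after the data were seen and are given with each comparison of neonatal aorta.

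Markers of other tissues varied within groups; the lists for skeletal muscle, squamous epithelium and thymocytes were added after the data were seen. Median log2 levels of the skeletal muscle list and of the squamous epithelium list were 13.5 and 13.2 on adult aorta 1, against 6.17 to 6.73 on the other adult aorta arrays. The squamous list also reached 11.4 on neonatal aorta 2. Krt13, a keratin of stratified epithelium, had a signal of 37297 on adult aorta 1. The thymocyte list had a median of 13.1 on neonatal valve 3 and 9.44 on neonatal valve 1, against 5.88 on neonatal valve 2. The cardiac muscle list was high in neonatal valve (13.0 to 13.1) and neonatal aorta (11.03 to 11.3), and in the adult valve it ran from 7.88 to 12.9.

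**Figure D2:**
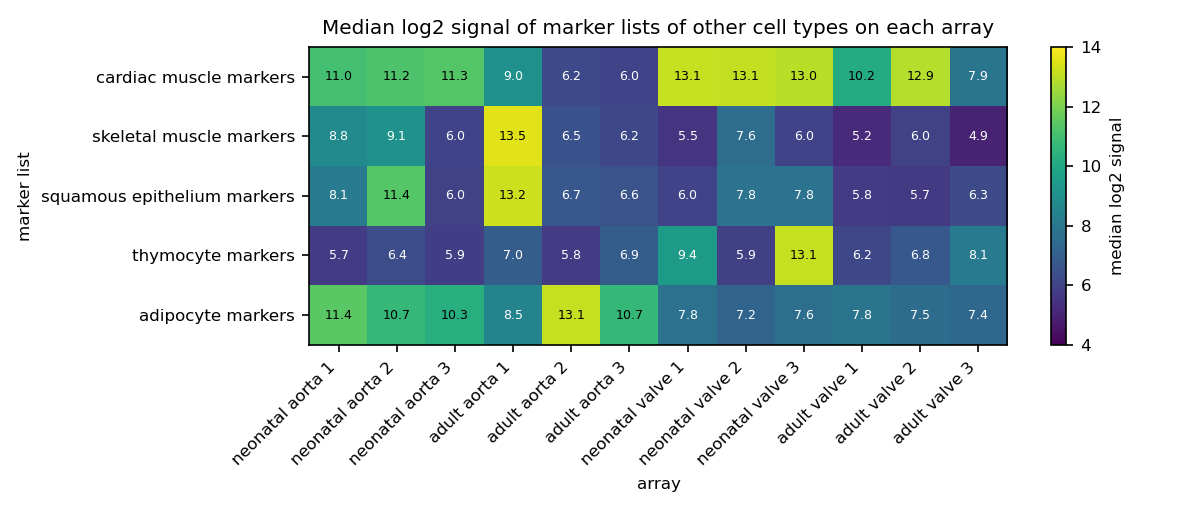
Median log2 signal (colour and printed value) of 5 marker lists of other cell types (vertical) on each of the 12 arrays (horizontal). Skeletal muscle and squamous epithelium markers stood out on adult aorta 1 and thymocyte markers on neonatal valve 3.

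Between the newborn and the adult aorta, the fetal growth programme was lower in the adult (n = 3 arrays in each group). Igf2 fell by 4.96 ± 0.38 (SE) in log2, a 31.0-fold difference (limma adjusted p = 0.00013). Dlk1, an imprinted gene of fetal mesenchyme, differed by -5.33 ± 0.54, and Meg3, a maternally expressed noncoding RNA, by -4.55 ± 0.44. P4ha3, which encodes a collagen prolyl hydroxylase subunit, fell 37.1-fold (-5.21 ± 0.34, adjusted p = 0.0001), and Fbn2, which encodes the fibrillin of developing microfibrils, differed by -6.71 ± 0.53 (adjusted p = 0.00015), with an adult signal of 13.8, at the level of absent control RNAs. Of 18552 probe sets, 1357 passed, 360 higher and 997 lower in the adult. With a change of at least 2-fold as well, 295 were higher and 836 lower.

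Lists of cell division, fetal growth and matrix genes had lower medians in the adult aorta. Of 39 measured members of the cell cycle list, 32 fell and 0 rose (38 fell, adjusted over the list alone), with a median of -2.58 (camera adjusted p = 3.8e-23). Ccne2, a cyclin of the entry into DNA replication, differed by -3.35 ± 0.33, and Mcm6, a subunit of the replicative helicase, by -2.77 ± 0.28. Of 14 imprinted and fetal growth genes, 12 fell (14 over the list alone; median -3.36, adjusted p = 1.9e-15), and this was the 1 list of this comparison whose call held with an estimated correlation (adjusted p = 0.0031). For the cell cycle list the adjusted p was 0.22 with an estimated correlation. Of 23 collagen genes 7 fell (11 over the list alone; median -1.34, adjusted p = 8.7e-07, 0.48 with an estimated correlation), among them Col16a1, a fibril-associated collagen (-2.29 ± 0.22), Col6a3, of microfibrillar collagen (-2.08 ± 0.21), and Pcolce, an enhancer of procollagen processing (-2.54 ± 0.32). Of 21 elastic fibre genes 5 fell (7 over the list alone; median -1.23, adjusted p = 4.0e-05, 0.48 with an estimated correlation), such as Fbln2, of the fibulin family (-3.04 ± 0.22), and Mfap2, a microfibril glycoprotein gene (-3.61 ± 0.29). Of 15 basement membrane genes 3 fell (6 fell and 1 rose over the list alone; median -0.60, adjusted p = 0.026, 0.61 with an estimated correlation), the laminin-binding Nid2 by -3.67 ± 0.40.

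Heart muscle genes were among the largest decreases in the aorta. Of 26 cardiac muscle genes 8 fell and 0 rose (8 over the list alone; median -2.77, camera adjusted p = 0.00011, 0.56 with an estimated correlation). Tnnt2, a troponin of the cardiac sarcomere, differed by -9.30 ± 1.15, Myh6, atrial myosin heavy chain, by -8.41 ± 1.13, and Myl2, a ventricular light chain, by -7.02 ± 0.65. Their adult aorta signals (geometric means 14.1, 44.3 and 11.9) were at the level of absent control RNAs. The troponin genes Tnni3 (-7.53 ± 0.82) and Tnnc1 (-5.48 ± 0.69), the myosin light chain genes Myl7 and Myl4 (-8.63 and -6.21), and Myh3, embryonic myosin (-7.25), fell with them. On neonatal aorta arrays Tnnt2 and Myh6 were bright (mean log2 13.12 and 13.88). Heart muscle carried over with the newborn tissue was not tested by age, and these decreases of heart muscle genes cannot be told apart from it. The other large decreases were in Prss35, a serine protease-like gene (-7.72), Pcp4, which encodes a calmodulin regulator (-7.50 ± 0.64), Clec3b, which encodes the plasminogen-binding tetranectin (-6.65), and Nrk, an embryonic kinase gene (-5.78). Mean adult aorta signals of Myl7 and Pcp4 were also at the level of absent control RNAs, so the size of their differences is not exact. In the smooth muscle contraction list the median was 0.76 (adjusted p = 0.0032, 0.63 with an estimated correlation), yet 1 of 23 genes rose and 1 fell (2 and 1 over the list alone): Pdlim3, a Z-disc protein gene, by 1.30 and the pericyte gene Rgs5 by -3.15 ± 0.44. Of 19 endothelial genes 1 fell, the VEGF receptor gene Kdr (-1.58; 0 over the list alone; median -0.95, adjusted p = 0.0021, 0.57 with an estimated correlation). Of 25 valve and outflow transcription factors 5 fell (9 over the list alone; median -1.22, or -0.78 without a filter, adjusted p = 0.016, 0.19 with an estimated correlation), including Hand2 (-2.37 ± 0.30) and Gata5 (-2.91 ± 0.44), regulators of heart development. Both were at the level of absent control RNAs in the adult aorta, and Gata5 stood at -1.50 with log2 of the signal plus 32.

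Among the 12 largest increases in the adult aorta were single genes of several functions. Aldh3a1, an aldehyde dehydrogenase gene, rose by 6.47 ± 1.22 and Akr1c15, an aldo-keto reductase gene, by 5.18 ± 0.70, both from the level of absent control RNAs. Aox1, aldehyde oxidase, rose 12.4-fold (3.63 ± 0.52). Npas2, a partner in the circadian activator complex, rose 16.4-fold (4.03 ± 0.39, adjusted p = 0.00043), and Cbx7, a Polycomb gene linked to resting cells, 14.3-fold (3.84 ± 0.35, adjusted p = 0.00034). Spetex2l1, a testis-associated transcript (4.59), Thrsp, a lipogenic regulator (4.38), and Plaat1, a phospholipid acyltransferase gene (4.26), also rose. Vxn, a neural regulator (4.10), Grm8, a glutamate receptor gene (4.02), Ngef, a gene of neuronal tissue (3.95), and Sorl1, a sorting receptor gene (3.71), completed the 12 largest. Of 17 clock genes 3 rose (4 over the list alone; median 0.41, adjusted p = 0.0045, 0.086 with an estimated correlation). Of 21 immediate early genes 1 rose, the stress-induced Atf3 (2.14 ± 0.37), and 8 over the list alone (median 0.80, adjusted p = 1.6e-05, 0.086 with an estimated correlation). Of 15 antigen presentation genes 2 rose, with Cd74, the class II invariant chain, at 2.13 (2 over the list alone; median 0.85, adjusted p = 0.00048, 0.48 with an estimated correlation).

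The other 15 lists did not pass in the aorta, though single members did. Agtr2, the fetal angiotensin receptor gene, differed by -5.76 ± 0.92 (2 of 21 vasoactive genes fell, 4 over the list alone), and Sfrp1, a secreted Wnt antagonist, by -2.02 ± 0.31 (of 24 Wnt genes 3 fell and 1 rose). Mmp14, a membrane-bound collagenase, differed by -2.00 ± 0.36 (3 of 23 proteases and inhibitors fell, 5 over the list alone), and Col11a1, a cartilage collagen, by -3.82 ± 0.42 (2 of 10 cartilage genes fell). Medians of the marker lists were 0.14 for adipocytes, -1.22 for red blood cells, -0.42 for macrophages, 0.43 for lymphocytes and 0.05 for melanocytes and Schwann cells. They were 0.03 for proteoglycans, 0.37 for bone, -0.37 for BMP and TGF-beta, -0.54 for Notch, 0.06 for fatty acid oxidation and -0.26 for Hox genes.

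With the control RNA batch as a block, 69 probe sets passed in the aorta, and 14 with only the arrays that held the controls, while all 1357 kept their direction in both. Both settings give the same estimate, that of neonatal aorta 1 alone against adult aorta, and differ only in the spread. That array is also part of the main mean, so a kept direction is no independent support. Of the 48 genes named for this comparison, 22 kept their call with the block, among them Fbn2, Igf2, P4ha3, Fbln2, Pcp4, Npas2 and Cbx7, and 9 with only those arrays. Within the batch the list medians were -2.56 for cell cycle, -3.22 for imprinted genes, -1.21 for collagens and -1.13 for elastic fibre, all still past. So were -2.62 for cardiac muscle, -1.01 for endothelium, 0.94 for smooth muscle, 0.76 for antigen presentation, 0.36 for clock and 1.03 for immediate early genes. The calls of basement membrane (-0.64) and of the valve transcription factors (-0.97) were lost. The count was 524 (120 higher, 404 lower) without neonatal aorta 1, 455 (114, 341) without neonatal aorta 2 and 431 (102, 329) without neonatal aorta 3. It was 812 (184 higher, 628 lower) without adult aorta 2 and 2485 (959, 1526) without adult aorta 1. With quantile normalization 595 were higher and 1172 lower. Without adult aorta 1 the medians were -0.67 for collagens, -0.41 for elastic fibre, -0.29 (not past) for basement membrane, 1.38 for smooth muscle, -4.88 for cardiac muscle and -0.71 for valve transcription factors. Bone (0.64) and adipocyte genes (0.76) then passed. Without adult aorta 2 they were -0.95 for basement membrane and 0.48 for smooth muscle, with Notch (-0.67) and proteases (-0.76) now past. Without adult aorta 3 they were -0.996 for basement membrane and 0.29 (not past) for smooth muscle, with fatty acid oxidation (0.37) and proteases (-0.92) now past. Without neonatal aorta 1, Notch (-0.65), adipocytes (0.17) and fatty acid oxidation (0.31) passed, and without neonatal aorta 3 basement membrane did not (-0.55). Calls of 8 genes depended on 1 array. Aldh3a1 lost its call without neonatal aorta 3 (5.51), Vxn without neonatal aorta 2 or 3 (3.43 and 3.92). Pdlim3 lost its call without neonatal aorta 1 or 2 or adult aorta 3 (1.10 to 1.27), and Cd74 without any 1 neonatal aorta array or adult aorta 1 or 2 (1.97 to 2.27). Thrsp (4.15 to 4.53), Myl7 (-8.82 to -7.73), Myl4 (-6.33 to -5.57) and Kdr (-1.71 to -1.16) lost theirs without any 1 neonatal aorta array. The same held for Thrsp, Myl4 and Kdr without adult aorta 3, for Myl7 and Myl4 without adult aorta 2 and for Kdr without adult aorta 1, and the difference of Thrsp was 2.89 without adult aorta 2.

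Between the newborn and the adult valve, cell cycle and fetal growth genes were lower in the adult (n = 3 arrays in each group). Igf2 fell 24.3-fold (log2 -4.61 ± 0.38 SE) and Meg3 22.3-fold (-4.48 ± 0.44). Igf2bp3, which encodes an RNA-binding protein of fetal tissue, differed by -9.14 ± 0.39 (limma adjusted p = 1.1e-06). Its adult valve signal (2.997) was at the level of absent control RNAs, and with log2 of the signal plus 32 the difference was -5.62. Among single genes that rose were Gsta1, a glutathione transferase gene, 27.9-fold (4.80 ± 0.34, adjusted p = 0.00017), Gda, guanine deaminase, 27.3-fold (4.77 ± 0.38, adjusted p = 0.00018), and Aox1 (5.19 ± 0.52, adjusted p = 0.00049). Of 18552 probe sets, 1709 passed, 742 higher and 967 lower, and with at least 2-fold as well 656 were higher and 767 lower. With each array centred on its median, 879 were higher and 672 lower.

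In the valve, too, cell division genes fell together. Of 39 cell cycle genes 33 fell and 0 rose (37 over the list alone; median -3.12, camera adjusted p = 4.2e-23, 0.42 with an estimated correlation), among them Aurkb, a mitotic kinase (-4.63 ± 0.54), Kif11, a spindle motor (-3.29 ± 0.41), and Ccne2 (-3.33 ± 0.33). Of 14 imprinted and fetal growth genes 10 fell (12 over the list alone; median -2.80, adjusted p = 5.4e-11), again the 1 list whose call held with an estimated correlation (adjusted p = 0.01). The largest decreases included Kif18b, a mitotic kinesin (-5.71), Hjurp, a centromere chaperone (-5.22 ± 0.64), and Myb, a transcription factor of proliferating cells (-5.92 ± 0.86). Cthrc1, a matrix protein of remodelling tissue (-5.73 ± 0.64), Col9a1, of cartilage collagen (-5.21 ± 0.76), Fbn2 (-5.62 ± 0.53), Agtr2 (-5.55 ± 0.92) and Bex1, a neurotrophin signalling gene (-5.18), fell as strongly. Of 26 cardiac muscle genes 3 fell (4 over the list alone; median -2.79, adjusted p = 6.3e-05, 0.58 with an estimated correlation). Here too, heart muscle carried over with the newborn tissue was not tested by age. The muscle genes Myh3 (-7.33 ± 1.23), Tnni1, slow skeletal troponin (-5.87 ± 0.90), and Acta1, skeletal actin (-5.35), were among the largest decreases. Of 25 fatty acid oxidation genes 4 fell (14 over the list alone; median -1.15, adjusted p = 6.5e-05, 0.58 with an estimated correlation), such as Cpt1b, the muscle carnitine transferase (-3.25), and Hadha, of the mitochondrial trifunctional protein (-1.64). Of 15 basement membrane genes 3 fell (3 over the list alone; median -0.76, adjusted p = 0.014, 0.58 with an estimated correlation), Nid2 by -2.84 ± 0.40.

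Macrophage and proteoglycan lists had higher medians in the adult valve, with part of their members past, and several single genes rose. Reg3g, an antibacterial lectin gene, rose 31.4-fold (4.97 ± 0.85), Lbp, which encodes a lipopolysaccharide-binding protein, 22.0-fold (4.46 ± 0.60), and Cytl1, a cytokine-like gene of cartilage, 22.2-fold (4.47 ± 0.57). Obp3, a lipocalin gene (6.75), Aldh3a1 (5.69), the cytokine gene Il1a (4.69), Fmo2, a monooxygenase gene (4.59), Dmbt1, a mucosal defence gene (4.49), and Omd, of the bone proteoglycan osteomodulin (4.43), were the other largest increases. Of 17 macrophage genes 5 rose (9 over the list alone; median 1.02, adjusted p = 2.2e-06, 0.42 with an estimated correlation), with Ctss, a lysosomal protease (2.04 ± 0.37), and Fcgr1a, an Fc receptor (1.86 ± 0.34). Of 21 proteoglycan genes 4 rose (5 over the list alone; median 0.58, adjusted p = 0.021, 0.42 with an estimated correlation), with Prelp (3.79 ± 0.69) and Dcn (1.00 ± 0.19), leucine-rich proteoglycans that bind collagen. Of 15 bone and calcification genes 2 rose (2 over the list alone; median 1.16, or 0.65 without a filter, adjusted p = 0.018, 0.42 with an estimated correlation), Ankh, a pyrophosphate exporter that restrains mineral, by 1.51 ± 0.30. Of 19 endothelial genes 2 rose and 1 fell (7 and 2 over the list alone; median 1.05, adjusted p = 0.008, 0.58 with an estimated correlation), Vwf, von Willebrand factor, by 2.02. Of 23 proteases and inhibitors 3 rose and 1 fell (7 and 3 over the list alone; median 0.80, adjusted p = 0.036, 0.58 with an estimated correlation): Adamts15, an aggrecan-cleaving protease (2.34 ± 0.42), and Ctsb, a lysosomal protease (1.34 ± 0.25), rose and Adam19, of heart cushion development (-2.05 ± 0.29), fell. Of 21 immediate early genes 2 rose (2 over the list alone; median 0.53, adjusted p = 0.017, 0.42 with an estimated correlation), Zfp36, an mRNA decay factor, by 1.34 ± 0.25. Of 15 antigen presentation genes 1 rose, B2m, the class I light chain (1.74 ± 0.30; 1 over the list alone; median 0.30, adjusted p = 0.045, 0.58 with an estimated correlation).

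For 2 lists of the valve that passed, members moved less clearly. Of 21 vasoactive genes 2 rose and 1 fell (2 and 1 over the list alone; median 0.66, adjusted p = 0.036, 0.58 with an estimated correlation), and of 28 BMP and TGF-beta genes 0 passed in limma, over all genes or over the list alone (median 0.27, adjusted p = 0.036, 0.58 with an estimated correlation). Cartilage genes split, with 2 of 10 higher, such as Comp, a matrix protein of load-bearing tissue (3.34 ± 0.60), and 4 lower, such as Col11a1 (-2.71 ± 0.42). Single members of other lists passed: P4ha3 (-2.55 ± 0.34) with 4 of 23 collagen genes lower, Mfap2 (-1.79 ± 0.29) among elastic fibre genes and Npas2 (2.12 ± 0.39) with 4 of 17 clock genes higher. Medians that did not pass were -0.52 for collagens, 0.48 for smooth muscle, 0.02 for adipocytes, 1.02 for red blood cells, -1.67 for lymphocytes and -0.13 for Hox genes.

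The valve count was 662 (305 higher, 357 lower) without neonatal valve 1, 853 (424, 429) without neonatal valve 2 and 893 (402, 491) without neonatal valve 3. It was 951 (475 higher, 476 lower) without adult valve 1 and 1137 (638 lower) without adult valve 3. Without adult valve 3, the median of smooth muscle genes was 1.34 and past, that of cardiac muscle -1.70, and basement membrane (-0.46) and endothelium (0.37) no longer passed. Proteoglycans lost their call without adult valve 1 or 2 (0.26 and 0.47) and immediate early genes without neonatal valve 2 (0.47). Proteases lost theirs without neonatal valve 3 (0.68) or adult valve 1 (0.64) or 2 (0.91), and vasoactive genes without neonatal valve 2 (0.73) or 3 (0.60) or adult valve 1 (0.48). BMP and TGF-beta genes lost theirs without neonatal valve 2 (0.25) or 3 (0.31) or adult valve 1 (0.29) or 3 (0.46), and stood at 0.46 without neonatal valve 1. Antigen presentation lost its call without neonatal valve 1 (0.26) or 2 (0.02) or adult valve 2 (0.14) or 3 (0.45), with 1.02 without neonatal valve 3 and 0.67 without adult valve 1. Collagens passed without neonatal valve 3 (-0.63) and red blood cell genes without adult valve 2 (1.71). Bex1 lost its call without neonatal valve 1 or adult valve 1 (-5.07 and -4.76), Aldh3a1 without neonatal valve 1 or 3 (5.82 and 5.14), and Obp3 without neonatal valve 1 or 3 or adult valve 1 (5.57 to 6.74). Vwf lost its call without neonatal valve 1 or 2 or adult valve 3 (1.72 to 1.98), and Fmo2 without neonatal valve 1 or 3 or adult valve 1 or 2 (3.58 to 4.31). Cpt1b (-3.14 to -2.82) and Hadha (-1.56 to -1.48) lost theirs without neonatal valve 1 or 2 or adult valve 1 or 3. Il1a (3.71 to 5.22) and Dmbt1 (3.44 to 5.06) did so without any 1 neonatal valve array or adult valve 2 or 3, Omd without any 1 neonatal valve array or adult valve 1 or 2 (3.68 to 4.73), and Acta1 without any 1 neonatal valve array or adult valve 3 (-5.41 to -3.80).

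The age differences of both tissues shared many probe sets. Of the 360 higher in adult aorta, 129 were also higher in adult valve (14.4 for independent lists), and 2 were lower there. Of the 997 lower in adult aorta, 410 were also lower in adult valve (52.0 for independent lists), and 4 were higher. Across the 18552 probe sets, which are not independent replicates, Pearson's r between the log2 differences was 0.51, and no array entered both comparisons.

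**Figure D3:**
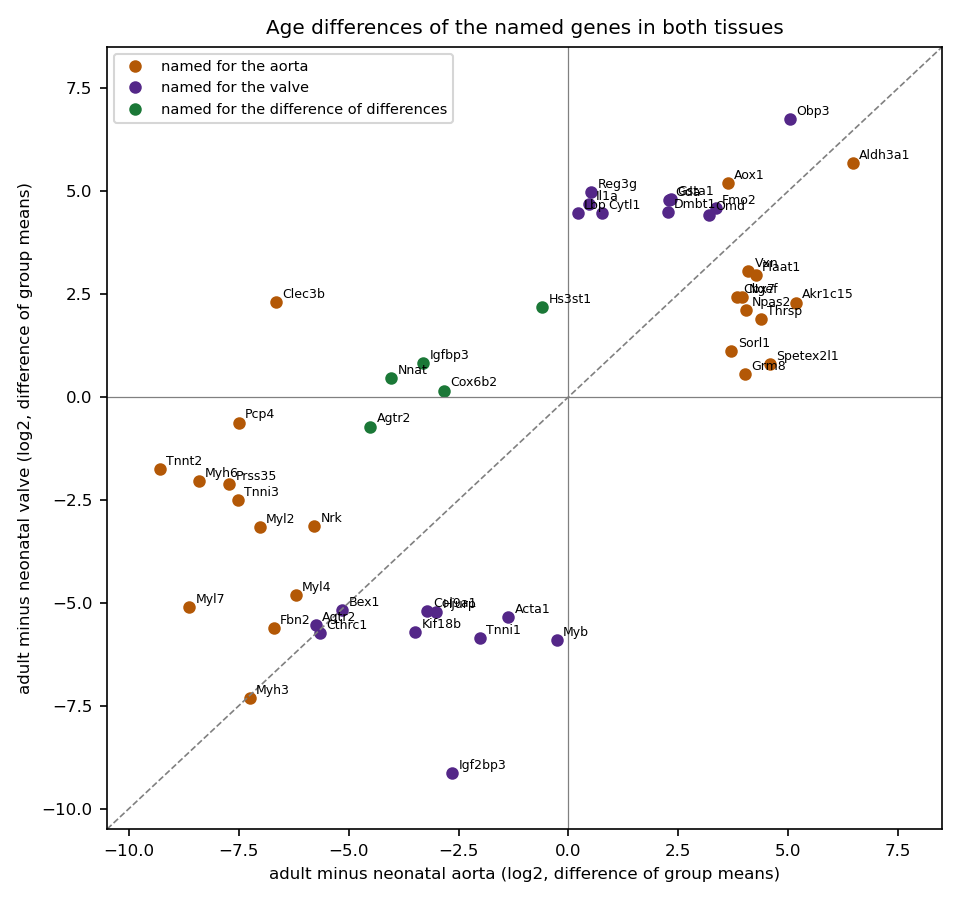
Difference of group means (log2, adult minus neonatal) in the aorta (horizontal) against that in the valve (vertical) for the genes with the largest differences in each tissue or between them; each point is 1 probe set, n = 3 arrays per group. Igf2bp3 lay far below the dashed line of equal differences and Pcp4 far above it.

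The difference between these age differences, tested directly, passed for 11 probe sets, 9 with a higher and 2 with a lower value in valve than in aorta (limma, n = 3 arrays in each of 4 groups; 2170 at an unadjusted p under 0.05). Igf2bp3 fell further in the valve by 6.50 ± 0.54 (SE) in log2 (adjusted p = 0.0019). Its adult valve signal was at the level of absent control RNAs, and with log2 of the signal plus 32 the difference was -3.43. Pcp4 fell in the aorta, to the level of absent control RNAs, and stayed low at both ages in the valve, a difference of 6.88 ± 0.91 (adjusted p = 0.031). Nnat, an imprinted proteolipid gene, had 4.49 ± 0.63 (adjusted p = 0.04), and Igfbp3, which encodes a carrier of IGF, 4.13 ± 0.61 (adjusted p = 0.049). Agtr2, at its probe set with the lower signal in newborn tissue, had 3.79 ± 0.45 (adjusted p = 0.031). At its brighter probe set Agtr2 differed by 0.21 and was not called with 1 probe set per gene, and neither was Igfbp3 (3.60). Cox6b2, a testis-type cytochrome oxidase subunit gene, had 2.99 ± 0.42, Hs3st1, a heparan sulfate sulfotransferase gene, 2.78 ± 0.35, and Fbln2 2.36 ± 0.31. Of the 11, 6 were called by age in the aorta only, 3 in the valve only, 1 in both in the same direction and 1 in both in opposite directions.

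By lists, 13 of 27 differed between the tissues in their age difference with the preset correlation, and 0 with an estimated correlation. The median difference was higher in the valve for endothelial genes (1.74, camera adjusted p = 4.7e-08, 0.33 with an estimated correlation), macrophage genes (1.74, adjusted p = 4.7e-08, estimated 0.33) and elastic fibre (1.36, adjusted p = 2.0e-06, estimated 0.33). The same direction held for collagens (0.94, adjusted p = 2.0e-05, estimated 0.38), proteases (1.20, adjusted p = 0.00028, estimated 0.37) and valve transcription factors (1.18, adjusted p = 0.00044, estimated 0.14). It held too for BMP and TGF-beta genes (0.89, adjusted p = 0.0031, estimated 0.33) and Notch (0.89, adjusted p = 0.0051, estimated 0.33), though Notch stood at 0.24 without a filter, still past. Higher medians were also found for proteoglycans (0.65), Wnt (0.99) and red blood cell genes (2.71; adjusted p = 0.029 for each, estimated 0.33, 0.33 and 0.49) and vasoactive genes (0.83, adjusted p = 0.027, estimated 0.49). Fatty acid oxidation was lower (-1.47, adjusted p = 7.1e-09, estimated 0.33). Over all genes 1 member of these lists passed, Fbln2. Adjusted over the list alone, 10 endothelial, 10 macrophage, 8 collagen, 5 elastic fibre, 5 protease, 2 Notch, 1 Wnt, 1 valve transcription factor and 1 vasoactive gene passed, all higher, and 0 of the other 4 lists (limma).

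With the control RNA batch as a block, 1 probe set passed for this difference, Igf2bp3 being the gene kept of the 8 named, and 0 with only the arrays holding the controls (of 8, 0 kept). Both rest on neonatal aorta 1 alone for that group and give the same estimates. Under either of these settings, proteoglycans lost their call (0.63) and smooth muscle (-0.80) and immediate early genes (-0.79) gained one. The other medians were 1.59 for endothelium, 1.79 for macrophages, 1.34 for elastic fibre, 0.85 for collagens and 1.08 for proteases. They were 1.05 for valve transcription factors, 0.84 for BMP and TGF-beta, 0.87 for Notch, 0.95 for Wnt, 3.49 for red blood cells, 0.61 for vasoactive genes and -0.91 for fatty acid oxidation. With the stricter filter 0 passed in limma, and the difference of Igf2bp3 was no longer called. The count was 1 without neonatal aorta 2 or 3, adult aorta 3, neonatal valve 1 or adult valve 3, and 2 without neonatal aorta 1, neonatal valve 3 or adult valve 2. It was 37 without adult aorta 1 or 2 and 35 without adult valve 1. Igf2bp3 passed in each of these. Pcp4 (6.15 to 7.17), Nnat (4.04 to 4.70), Agtr2 (3.58 to 3.86), Igfbp3 (3.79 to 4.38), Cox6b2 (2.79 to 3.20), Hs3st1 (2.63 to 2.90) and Fbln2 (2.16 to 2.47) each lost their call without neonatal aorta 1, 2 or 3, adult aorta 3, neonatal valve 1 or 3 or adult valve 3. The same held without adult valve 2 except for Agtr2, and without neonatal valve 2 for Igfbp3, Cox6b2 and Fbln2. Without adult aorta 1, collagens (0.26), proteoglycans (0.41), red blood cells (2.21), Wnt (0.36), BMP and TGF-beta (0.56) and vasoactive genes (0.01) lost their calls, and elastic fibre stood at 0.47 and proteases at 0.56. Adipocytes (-1.39), basement membrane (-0.84) and smooth muscle (-1.18) gained a call. Proteoglycans also lost theirs without neonatal aorta 3 (0.67), neonatal valve 2 (0.69) or 3 (0.65) or adult valve 1 (0.61) or 2 (0.60), and red blood cells without neonatal aorta 1 (2.29), neonatal valve 3 (2.85) or adult valve 3 (0.81). Vasoactive genes lost theirs without neonatal valve 3 (0.73) or adult valve 1 (0.39) and Wnt without neonatal valve 2 (0.99), and proteases stood at 0.74 without adult valve 1. Calls were gained for smooth muscle without adult valve 1 (-1.01), for cell cycle genes without adult aorta 2 (-0.58) or adult valve 3 (-0.61), and for immediate early genes without neonatal aorta 3 (-0.23) or adult valve 1 (-0.31). They were also gained for lymphocytes (-2.998) and antigen presentation (-0.32) without neonatal valve 2, and for melanocyte and Schwann genes without neonatal valve 1 (-1.24).

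Between neonatal valve and neonatal aorta, fat genes and heart peptide genes set the tissues apart (n = 3 arrays in each group). A different amount of fat in the samples was tested only by age, not between tissues. Ucp1 ran from 295 to 5394 on neonatal aorta arrays. Adipoq, the adipocyte hormone adiponectin, was lower in the valve (log2 -6.77 ± 0.93 SE, limma adjusted p = 0.0005), and so was Ucp1, the uncoupling protein of brown fat (-8.71 ± 1.84), both to the level of absent control RNAs. Nppb and Nppa, natriuretic peptide genes of heart muscle, were higher (6.34 ± 0.97 and 6.81 ± 1.82), and Gata4, a transcription factor of heart and valve, was 6.11-fold higher (2.61 ± 0.42). The largest difference was in Xist (9.29 ± 1.16), and Eif2s3y was lower (-7.30 ± 1.12). Xist in the aorta and Eif2s3y in the valve had mean signals at the level of absent control RNAs. Of 18552 probe sets 6043 passed, 2461 higher and 3582 lower in the valve, and with at least 2-fold as well 1650 and 2899. After centring on array medians, 4116 were higher and 2305 lower, since this moved the median of all tested probe sets from -0.09 to 0.27. Among 649 genes with at least 2 called probe sets, 240 (37.0%) had calls in opposite directions, against 0 of 102 and 0 of 118 in the age comparisons of aorta and valve.

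Most lists that set the neonatal tissues apart were lower in the valve, and each had an adjusted p of 0.69 with an estimated correlation. Of 18 adipocyte genes 11 fell and 1 rose (13 and 1 over the list alone; median -2.70, camera adjusted p = 0.0011), with Fabp4, a lipid carrier (-5.19 ± 0.84), Cfd, adipsin (-4.53 ± 0.63), and the lipid droplet genes Plin1 (-6.76 ± 1.03) and Cidec (-7.30 ± 1.51). Other fat or lipid metabolism genes among the largest decreases were Pck1, of glyceroneogenesis (-6.60), Trarg1, of glucose transporter traffic (-6.56), and the adipogenic factor Cebpb (-6.39). Of 11 Hox genes 8 fell (11 over the list alone; median -2.04, adjusted p = 0.0017), such as Hoxa7 (-4.83 ± 0.84) and Hoxb3 (-1.75 ± 0.41), which mark position along the body axis. With log2 of the signal plus 32, Hoxa7 stood at -2.55 and Cidec at -4.82. Of 17 macrophage genes 9 fell and 1 rose (10 and 2 over the list alone; median -1.35, adjusted p = 0.0039), with the receptor adaptors Tyrobp (-2.78 ± 0.42) and Fcer1g (-1.90 ± 0.35). Of 21 vasoactive genes 9 fell (13 fell and 1 rose over the list alone; median -1.50, adjusted p = 0.0039), with Pde5a, a phosphodiesterase of smooth muscle (-3.23 ± 0.41), and the prostaglandin receptor gene Ptger3 (-2.11 ± 0.35). Of 26 cardiac muscle genes 3 rose (3 over the list alone; median 1.59, adjusted p = 0.0039).

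Of the matrix lists, those for collagens, elastic fibre and proteoglycans had lower medians in neonatal valve than in neonatal aorta, while basement membrane (-0.25) and cartilage (1.13) did not pass. Of 23 collagen genes 7 fell (7 over the list alone; median -0.93, adjusted p = 0.0039), with Pcolce (-2.14 ± 0.32) and Col16a1 (-1.09 ± 0.22). Of 21 elastic fibre genes 4 fell (3 over the list alone; median -1.02, adjusted p = 0.0054), with Fbln2 (-2.27 ± 0.22) and Mfap2 (-1.45 ± 0.29). Of 21 proteoglycan genes 5 fell (5 over the list alone; median -0.93, adjusted p = 0.039), with the cell-surface gene Sdc4 (-1.76 ± 0.33). Of 23 proteases and inhibitors 7 fell and 1 rose (7 and 1 over the list alone; median -0.90, adjusted p = 0.015), with Htra3, a serine protease of TGF-beta control (-2.61 ± 0.44), and Timp1, a metalloprotease inhibitor (-2.03 ± 0.39). After centring on medians, collagens, proteoglycans and proteases stood at -0.60, -0.59 and -0.57, still past. Among lists that did not pass, Notch had Jag1, a ligand of vessel development (-2.14 ± 0.30), and its target Heyl (-3.28 ± 0.56) with 4 of 12 lower. Wnt had Sfrp4 (-3.07 ± 0.37) and Wnt5a (-2.37 ± 0.51) with 5 of 24 lower and 1 higher, and BMP and TGF-beta had Bmpr2, a receptor, higher (1.50 ± 0.19) and its target Id3 lower (-3.28 ± 0.44), 4 and 6 of 28. Of 25 valve transcription factors 2 rose and 5 fell, with Foxc2, of lymphatic and valve development, at -4.41 ± 0.91 (-2.82 with log2 of the signal plus 32). Of 23 smooth muscle genes 3 fell (median -1.31), with the actin gene Acta2 at -3.75 ± 0.96. In the cell cycle list 0 of 39 passed in limma, over all genes or over the list alone (median 0.25). Medians of the other marker lists were -0.46 for red blood cells, 1.46 for lymphocytes and -0.50 for endothelium, and did not pass.

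Among the remaining large differences, Hils1, a spermatid histone-like gene (5.22), Myb (4.49 ± 0.86), Ntsr2, a neurotensin receptor gene (4.51), LOC102553868, an uncharacterized locus (4.79), and Slc16a12, a creatine transporter gene (3.93 ± 0.54), were higher in neonatal valve, and Clec3b was lower (-6.30). For Nefh, a neurofilament gene (5.77), Ryr2, the cardiac calcium channel (4.82), Rnf207, a cardiac ubiquitin ligase gene (4.34), Camta1, a transcription activator gene (3.77), Ubl7, a ubiquitin-like gene (-7.20), Ppp3r1, a calcineurin subunit gene (-6.94), and the chemokine gene Cxcl12 (-5.52), the call depended on the probe set or on the number of tests. Tested with 1 probe set per gene, the one with the highest mean, none of these 7 passed, at 5.77 (the same probe set of Nefh), 2.04, 2.10, 0.57, -0.64, -0.30 and -1.22.

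For the neonatal tissues, 1416 probe sets passed with the control RNA batch as a block and 641 with only the arrays that held the controls, and all 6043 kept their direction in both. Here too the estimate is that of neonatal aorta 1 alone, the same in both settings, and a kept direction is no independent support. Of the 48 genes named, 31 kept their call with the block, Adipoq, Ucp1, Nppb, Gata4 and Xist among them, and 18 with only those arrays. The list medians within the batch were -3.34 for adipocytes, -1.77 for Hox, -1.48 for macrophages, -1.26 for vasoactive genes, 1.81 for cardiac muscle, -0.88 for collagens, -0.89 for elastic fibre and -0.79 for proteases, all past, and -0.85 for proteoglycans, which were not. Proteoglycans also lost their call without neonatal aorta 3 (-0.81) or neonatal valve 2 (-0.94) or 3 (-0.70), and smooth muscle passed without neonatal aorta 1 (-1.44) or neonatal valve 1 (-1.47). Cardiac muscle (1.92) lost its call with centring on medians. The number higher was 1543 without neonatal aorta 2 and 1580 without neonatal aorta 3. Nppa lost its call without neonatal aorta 3 (6.08), Nefh without neonatal aorta 1 or 3 or neonatal valve 1 or 3 (4.64 to 5.55), and Ryr2 without any 1 of the 6 arrays (3.83 to 5.48).

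Between adult valve and adult aorta, some genes of heart development and of endothelium were higher in the valve, and most adipocyte and fatty acid oxidation genes measured were lower (n = 3 arrays in each group). Hand2 (log2 3.60 ± 0.30 SE, limma adjusted p = 4.1e-05) and Gata5 (3.50 ± 0.44) were higher, from the level of absent control RNAs in the aorta, and Gata4 was 13.8-fold higher (3.79 ± 0.42). Comp was 16.3-fold higher (4.03 ± 0.60), Vwf 5.95-fold (2.57 ± 0.44), and Fabp4 51.2-fold lower (-5.68 ± 0.84). Fat genes varied widely among adult aorta arrays, with Adipoq at 634 to 8805 and Ucp1 at 302 to 37326. A different amount of fat in the samples was not tested between these tissues either. Of 18552 probe sets 6891 passed, 3207 higher and 3684 lower in the valve, and with at least 2-fold as well 2307 and 2993. After centring on array medians, 5374 were higher and 2177 lower, since this moved the median of all tested probe sets from -0.05 to 0.37 (0.10 with quantile normalization). Among 775 genes with at least 2 called probe sets, 322 (41.5%) had calls in opposite directions.

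By lists, 7 passed between the adult tissues, each with an adjusted p of 0.93 with an estimated correlation. Of 18 adipocyte genes 15 fell (16 over the list alone; median -3.03, camera adjusted p = 8.3e-06), with Dgat2, of triglyceride synthesis (-5.08 ± 0.61), Cfd (-3.34 ± 0.63) and Cidec (-5.66), and Ucp1 was lower (-8.48 ± 1.84), to the level of absent control RNAs. Of 25 fatty acid oxidation genes 16 fell (20 over the list alone; median -1.62, adjusted p = 8.3e-06), with Ucp3, a mitochondrial carrier (-3.27 ± 0.53), Acaa2, a thiolase (-2.62 ± 0.55), and Hadha (-1.70 ± 0.38). Of 23 smooth muscle genes 6 fell (2 over the list alone; median -1.72, adjusted p = 0.0089), with Acta2 (-4.33 ± 0.96) and Smtn, of contractile smooth muscle (-1.94 ± 0.42). Of 11 Hox genes 5 fell (6 over the list alone; median -1.93, adjusted p = 0.0089), with Hoxb3 (-2.21 ± 0.41) and Hoxc4 (-3.73 ± 0.80). Of 19 endothelial genes 6 rose (6 over the list alone; median 1.19, adjusted p = 0.0089), with the receptor genes Tek (2.49 ± 0.46), Eng (2.46 ± 0.49) and Flt1 (1.94 ± 0.39). Of 26 cardiac muscle genes 8 rose (8 over the list alone; median 1.82, adjusted p = 0.0089), with Tnnt2 (8.55 ± 1.15), Myh6 (6.68 ± 1.13), Tnni3 (5.84 ± 0.82), Nppb (5.63 ± 0.97) and Myl2 (5.48 ± 0.65). The aorta signals of Tnnt2, Myh6 and Myl2 were at the level of absent control RNAs, so the size of these differences is not exact. Of 25 valve transcription factors 9 rose and 3 fell (9 and 3 over the list alone; median 0.85, adjusted p = 0.047).

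Single genes of other lists differed between the adult tissues. Medians of marker lists that did not pass were 2.17 for red blood cells, 0.56 for macrophages and 0.21 for lymphocytes. Of 10 cartilage genes 4 rose and 1 fell, with Hapln1, a hyaluronan link protein (2.40 ± 0.62), and Cilp2, a cartilage layer protein (3.49 ± 0.91), beside Comp. Bmpr2 (2.13 ± 0.19), the protease gene Adamts5 (1.50 ± 0.27) and Rbpj, the Notch transcription partner (1.27 ± 0.19), were higher, while a second called probe set of Rbpj and one of Flt1 were lower. Among the largest differences, Xist (9.47 ± 1.16), Coch, an extracellular matrix gene (8.15 ± 1.57), Reg3b (6.99 ± 0.96) and Reg3g (6.31 ± 0.85), antibacterial lectins, were higher. So were Gpr182, an endothelial chemokine scavenger gene (5.85 ± 0.64), Meox1, a mesodermal homeobox gene (5.02 ± 0.76), and Bod1l1, a replication fork protein gene (4.94 ± 0.54). Eif2s3y (-8.78 ± 1.12), Tgfb1, the growth factor of matrix deposition (-5.72 ± 0.82), and Atp5mg, an ATP synthase subunit gene (-5.71 ± 0.27), were lower. Xist in the aorta and Eif2s3y in the valve were again at the level of absent control RNAs. With log2 of the signal plus 32, Tgfb1 stood at -3.30 and Bod1l1 at 3.25, so the size of their differences is not exact. Ubl7 (-7.33), the mitochondrial genes Immt (-6.38) and Uqcrc2 (-6.17), Plekhb2, of recycling endosomes (-5.86), and the caveola genes Cav1 (-5.79) and Cav2 (-5.64) were lower at these probe sets. At the brightest probe set of each gene they did not pass, at -0.54, -0.75, -1.004, 0.18, 0.30 and 0.11.

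For the adult tissues, the count stayed between 5692 and 7048 whichever array was left out. Of the 46 genes named, Cidec alone lost its call, without adult aorta 2 (-4.40) or adult valve 3 (-4.62). Without adult aorta 1 the median of cardiac muscle was 3.94, and basement membrane (-0.69) and vasoactive genes (-0.88) passed. Without adult aorta 2 adipocytes stood at -1.99 and fatty acid oxidation at -1.07, and without adult valve 3 cardiac muscle at 3.00. Calls were lost for Hox (-2.03 and -1.47), endothelium (0.68 and 0.68) and smooth muscle (-1.08 and -0.59) without adult aorta 3 or adult valve 3, and for cardiac muscle without adult aorta 2 (0.94) or 3 (0.81) or adult valve 2 (0.48). The valve transcription factors lost theirs without adult aorta 1 (0.48) or 3 (0.97) or adult valve 1 (0.88) or 2 (0.64), and with centring on medians (1.56), as cardiac muscle did (2.21).

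The tissue differences at both ages overlapped. Of the 2461 higher in neonatal valve, 1641 were higher in adult valve too (425 for independent lists), and 10 were lower. Of the 3582 lower, 2478 were lower in adult valve too (711 for independent lists), and 25 were higher. Pearson's r across the 18552 probe sets was 0.72, with no array in both comparisons. Valve arrays of both ages shared the higher 3' to 5' ratio, also in added RNAs, and the Xist signal. Both comparisons carry these differences, so neither their calls nor the overlap show tissue alone. Between the 2 brightest probe sets of a gene, r was 0.40 between neonatal and 0.41 between adult tissues. By age it was 0.74 in the aorta and 0.74 in the valve.

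For some lists that did not pass, median, mean and direction of the test differed in sign. In the age comparisons these were proteoglycans in the aorta (median 0.03, mean -0.01, test up), and in the valve elastic fibre (0.00, -0.17, up), valve transcription factors (-0.17, -0.04, up) and Hox genes (-0.13, -0.18, up). Between neonatal tissues they were antigen presentation (-0.17, 0.16, up), valve transcription factors (-0.16, -0.24, up) and immediate early genes (-0.08, 0.06, up). Between adult tissues they were cell cycle (0.19, -0.02, up), bone (-0.31, -0.08, up), lymphocytes (0.21, -0.17, down), antigen presentation (0.01, -0.15, down) and proteases (-0.13, 0.19, up). For the difference of the age differences they were cardiac muscle (-0.36, 0.47, up) and antigen presentation (0.06, -0.31, down). No list that passed reversed under any scaling.

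**Figure D4:**
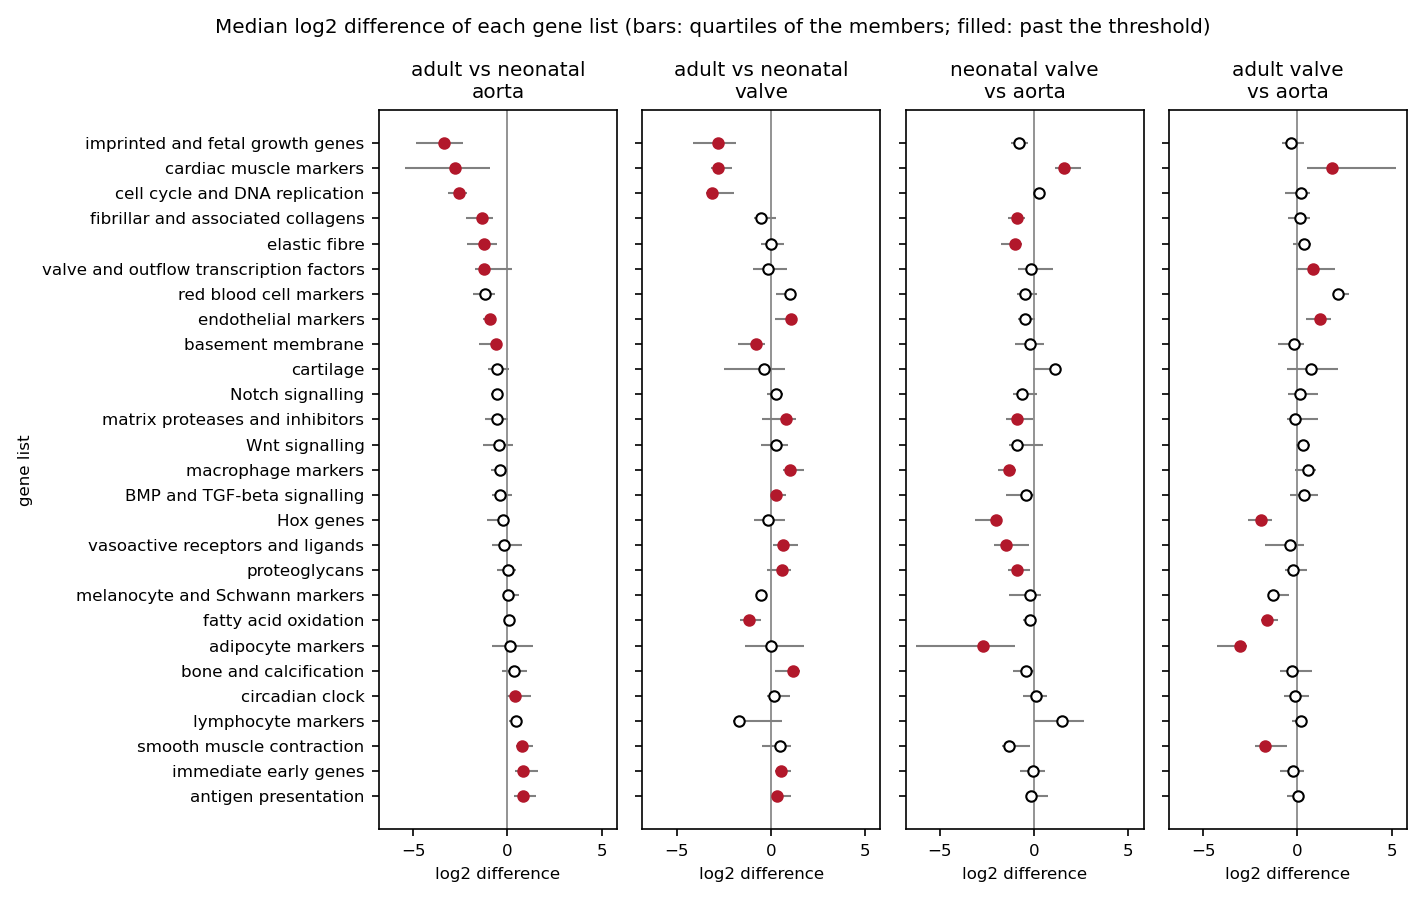
Median log2 difference of each gene list (points, filled where the list passed with the preset correlation) with the quartiles of its members (bars) for the comparisons of adult with neonatal tissue and of valve with aorta, n = 3 arrays per group. Cell cycle and imprinted genes were lower in both adult tissues (medians of -3.36 to -2.58), and adipocyte genes were lower in valve than in aorta at both ages (-2.70 and -3.03).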

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

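Tests of 3' bias, of degraded RNA, of sex, of adult aorta 1 and of Xist were chosen only after the results were seen, while those of exchanged labels, of neonatal RNA under an adult label, of carried-over heart muscle and of other splits of the samples were planned.

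A difference between the tissues in their age difference, tested directly, singled out these genes among its largest values: Pcp4 (6.88), Nnat (4.49), Igfbp3 (4.13), Agtr2 (3.79 at its dimmer probe set, 0.21 at the brighter one), Cox6b2 (2.99), Hs3st1 (2.78) and Igf2bp3 (-6.50, or -3.43 with log2 of the signal plus 32), as log2 values in valve minus aorta. Fbln2, a list member, passed as well (2.36). The same test singled out lists for collagens (0.94), elastic fibre (1.36), proteoglycans (0.65), endothelium (1.74), red blood cells (2.71), macrophages (1.74), Wnt (0.99), BMP and TGF-beta (0.89), Notch (0.89), valve transcription factors (1.18), fatty acid oxidation (-1.47), proteases (1.20) and vasoactive genes (0.83). With an estimated correlation 0 of these 13 lists passed (adjusted p 0.14 to 0.49), and 6 lost their call without adult aorta 1. Of 100 splits drawn at random, the real one included, 7 gave at least as many probe sets as the real 11, and the highest other split gave 3415, so chance cannot be excluded for this count by these splits. The splits with the highest counts joined the neonatal valve arrays with mostly adult aorta arrays, which brings in the age difference itself. Their counts point to age as a structure of the samples and make them a poor measure of chance for this difference.

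Control probe sets that no comparison uses drew attention to the valve arrays, whose beta-actin 3' to 5' ratio had a geometric mean of 9.92. If a stronger 3' bias acts on the valve arrays, probe sets of a gene should split by position, and 37.0% of genes with several calls had them in opposite directions between neonatal tissues (41.5% between adult tissues), against 0 of 102 and 0 of 118 by age. Degradation of tissue RNA as the whole cause was argued against by the dap control, which does not come from the tissue, whose lowest log2 ratio on valve arrays exceeded the highest on spiked aorta arrays by 2.77. Sex could not be separated from tissue, since Xist followed tissue: 32.9% of X-linked and 32.9% of autosomal probe sets passed between neonatal tissues, and 42.4% and 37.5% between adult tissues. Heart muscle carried over with the valves may account for part of the adult difference, where the cardiac list had a median of 1.82 and 3 of 4 abundant markers were higher and past. At the neonatal age the test could not decide (1.59, 0 of 4 higher and past). Myh6 was bright in both neonatal tissues (mean log2 13.88 in aorta and 14.20 in valve). A difference between tissues cannot show heart muscle that is present in both. The requirement on abundant markers was added after the values were seen, and tissue itself stays open, as untested.

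Adult aorta 1 stood apart from the other adult aorta arrays. Skeletal muscle and squamous epithelium in the sample may explain this: the squamous list without Krt5, the gene first seen, was 6.78 higher in log2 than on the higher of the other arrays, and the skeletal muscle list without Myh4 and Myh1 was 7.23 higher. A neonatal aorta sample in its place was argued against by imprinted genes, which lay 3.41 below the lowest neonatal aorta array in their median, although H19, 1 gene of that kind, had a signal of 18157, within the neonatal range of 14554 to 22817. Scaling of the array was argued against by quantile normalization, after which the squamous list was still 6.69 higher. No biological explanation was tested.

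Labels conflicted in 6 samples, and adult valve arrays labelled male carried Xist. Exchanged titles of adult aorta and neonatal valve were argued against by the cell cycle list, with a median 2.80 lower (-2.80) on arrays titled adult aorta than on arrays titled neonatal valve. An adult sample with neonatal RNA was argued against by imprinted genes, by which adult aorta lay further from neonatal aorta than from adult valve by 2.54. The Xist difference of 9.47 between adult valve and adult aorta is consistent with a sex label or a sample source that differs from the label, and noise of a single probe set was argued against by 4 of 4 Xist probe sets. By these values the 6 samples follow their titles, and whether the sex label or the sample source of the valves is wrong stays open.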

How the results depend on the processing

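The alternatives without the doubted arrays (adult aorta 1 and neonatal valve 3), with only arrays with poly-A spike controls, and with the spike control batch as a block were chosen only after the results were seen.

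Counts within 1.5 times the main count are not listed here unless stated, and where no construction is named the cause was not tested. With the stricter filter, which tests fewer probe sets, 3700 passed between neonatal tissues (1853 lower), 4299 between adult tissues (1830 lower) and 0 for the difference of age differences. That last count was 7 without the intensity trend and 1 with the replicate number as a block, although the numbers do not pair the arrays: residual correlations of 18 pairs with the same number ran from -0.31 to 0.24, with 3 over 0.1. With only the groups compared, which leaves fewer arrays for the spread, 811 passed in the aorta by age and 3646 between adult tissues. With 1 probe set per gene, which tests fewer probe sets, counts were 814 and 1101 by age in aorta and valve, 2599 and 3285 between neonatal and adult tissues, and 6 for the difference of age differences. There Plekhb2 (0.18), Cav1 (0.30) and Cav2 (0.11) reversed between adult tissues, at another probe set of the gene. Groups by description and tissue exchange the comparisons by construction: 6043 for adult against neonatal aorta, 6891 for adult against neonatal valve, 1357 between neonatal and 1709 between adult tissues. Without the doubted arrays, 2483 passed in the aorta by age and 5 for the difference of age differences. With only arrays holding the spike controls, which leaves 1 neonatal aorta array assumed to vary like the others, 14 passed in the aorta by age, 641 between neonatal tissues and 0 for the difference. With that batch as a block, which rests on the same estimates, the counts were 69, 1416 and 1. Without each array in turn, counts ran from 431 to 2485 and from 662 to 1514 by age in aorta and valve, and from 1 to 37 for the difference of age differences.

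Groups by description and tissue were run for counts only, and kept the direction of 63.1%, 69.8%, 61.6% and 65.5% of the calls of these comparisons, in the order above. Among the alternatives run for lists and genes, those 3 genes were the reversals. List calls kept in every fit with 1 array left out were 10 of 12 and 6 of 14 by age in aorta and valve, 8 of 9 and 2 of 7 between neonatal and adult tissues, and 7 of 13 for the difference. With log2 of the signal plus 32, all 198 gene calls were kept at a median of 88.3% of the main value (51.6% to 99.8%), with 22 moved by more than 1.5 times, such as Igf2bp3 (-3.43 for the difference) and Ucp1 (-5.62 between neonatal tissues), by construction at dim signals. Other list calls ended as follows. With the stricter filter these were valve transcription factors (-1.06) and clock (0.23) in the aorta by age, antigen presentation (0.46), BMP and TGF-beta (0.26) and vasoactive genes (0.84) in the valve by age, vasoactive genes between neonatal tissues (-1.19), cardiac muscle (1.82) and endothelium (1.04) between adult tissues, and proteoglycans for the difference (0.72). With quantile normalization they were smooth muscle in the aorta by age (0.60), BMP and TGF-beta in the valve by age (0.29) and proteoglycans between neonatal tissues (-0.84). With centring on medians they were antigen presentation (0.40), BMP and TGF-beta (0.35) and proteases (0.89) in the valve by age. Without the doubted arrays, elastic fibre in the aorta by age (-0.41) and, for the difference, collagens (0.11), proteoglycans (0.30), red blood cells (2.35), Wnt (0.30), BMP and TGF-beta (0.46), proteases (0.37) and vasoactive genes (-0.09, a median of the other sign, with the direction of the test unchanged) lost their calls. With log2 of the signal plus 32 these were antigen presentation (0.19) and BMP and TGF-beta (0.22) in the valve by age and valve transcription factors between adult tissues (0.75), which also ended without the trend and with only the groups compared (0.85). Proteoglycans between neonatal tissues ended without the trend (-0.93) and basement membrane in the aorta by age with only the groups compared (-0.60). Valve transcription factors between adult tissues stood at 1.35 with the stricter filter and Hox genes at -1.23 with log2 of the signal plus 32, both still past. Wnt passed in the valve by age (0.63) and lymphocytes for the difference (-1.77) without a filter. Smooth muscle passed between neonatal tissues with centring on medians (-0.98), with the stricter filter (-1.29) and with only the groups compared (-1.31). Of the named genes, calls ended with only the groups compared for Aldh3a1, Thrsp, Vxn, Kdr, Gata5 and Pdlim3 in the aorta by age, for Il1a and Fmo2 in the valve by age and for Cidec and Hapln1 between adult tissues. For the difference of age differences, Nnat, Igfbp3 and Fbln2 lost their calls without the trend, Igfbp3 and Fbln2 with centring on medians and Cox6b2 without a filter. In the aorta by age, calls also ended for Myl4 and Kdr with centring on medians, for Myl4, Kdr and Cd74 without a filter and again without the trend, for Myl4 and Cd74 with the replicate block, for Pdlim3 with quantile normalization, for Myl4 with 1 probe set per gene and for Kdr and Pdlim3 without the doubted arrays. In the valve by age they ended for Il1a with quantile normalization, Il1a and Dmbt1 with the replicate block and Fmo2 without the doubted arrays. Between neonatal tissues they ended for Nefh with quantile normalization and the stricter filter, and for Nefh and Ryr2 with the replicate block and without the doubted arrays. For the difference, all but Igf2bp3 ended with the replicate block, every gene tested with the stricter filter, and Nnat, Igfbp3, Cox6b2, Hs3st1 and Fbln2 without the doubted arrays. Signal over background on 3 arrays per group limits the smallest change that can be called.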

Other observations

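Tests of other cell types by age and of the splits of samples were planned, and none in this part was chosen after the result was seen; the examples of single genes were.

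Genes called for the difference of age differences were brightest in different groups, and few were confined to 1 of them. They were picked by that test. Of those given here, all but Igf2bp3 lost their call in 8 or 9 of 12 fits with 1 array left out. Geometric mean signals of Pcp4 were 3354 in neonatal aorta, 18.5 in adult aorta, 136 in neonatal valve and 88.2 in adult valve. Nnat had 7928, 485, 267 and 368 in the same order, and Cox6b2 609, 85.4, 139 and 154. Igf2bp3 was brightest in neonatal valve (1693, against 446 in neonatal aorta, 71.5 in adult aorta and 2.997 in adult valve), and Hs3st1 in adult valve (950.1, against 433, 286 and 209 in neonatal aorta, adult aorta and neonatal valve). Igfbp3 was high in all but adult aorta, with 2797, 282, 1440 and 2536.

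Single arrays of a group differed widely in some genes. Eln, the elastin gene, had signals of 19063 to 20456 on neonatal aorta arrays and of 349 to 19375 on adult aorta arrays. H19, an imprinted noncoding RNA of fetal tissue, had signals of 14554 to 22817 on neonatal aorta arrays, 9604 to 12338 on neonatal valve arrays, 319 to 371 on adult valve arrays and 225 to 18157 on adult aorta arrays, the highest on adult aorta 1. Ucp1 ran from 302 to 37326 on adult aorta arrays. Cd3e, a T cell receptor gene, ran from 4.26 to 3647 on neonatal valve arrays.

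Planned tests of other cell types by age gave list medians furthest from 0 of -1.22 for red blood cells in the aorta and of -1.67 for lymphocytes in the valve, both beyond the bound of 1 set beforehand, though neither list passed. The red blood cell list in the aorta did pass with only the groups compared (adjusted p = 0.042). The others were 0.14 for adipocytes, -0.42 for macrophages and 0.43 for lymphocytes in the aorta, and 0.02 for adipocytes, 1.02 for red blood cells and 1.02 for macrophages in the valve. Of the lists beyond the bound, macrophages in the valve passed (camera adjusted p = 2.2e-06, 0.42 with an estimated correlation). For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. As many probe sets as the real split came from 1 split, the real one, in each comparison: adult against neonatal aorta 1357 (highest other 0), adult against neonatal valve 1709 (highest other 1), neonatal valve against neonatal aorta 6043 (highest other 0) and adult valve against adult aorta 6891 (highest other 108).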
